A study of Mus musculus with 9 samples.

How the data were processed

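RNA from the intestinal tract of mice was sequenced under 9 conditions, with 1 library per condition. Per the labels, tissue was homogenised in ISOGEN for RNA extraction, ribosomal RNA was removed with a Ribo-Zero Plus kit, and stranded TruSeq libraries were made without the bead step that selects mRNA, so RNAs without a poly(A) tail were kept. The submitters' processing notes name HISAT2 (no version stated), Cuffdiff 2.2.1 and the genome build GRCm38. The deposited table gives, per the file headers, FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 55468 genes in each of the 9 libraries. The gene annotation used by the authors, and whether a library came from 1 animal or from a pool, are not given in the sources used here. Gene types and GRCm38 coordinates were taken from GENCODE M21, in which 327 of the genes were not found.

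The table holds no counts. The number of fragments per library was estimated from the step between the smallest FPKM values of genes with a single annotated transcript, and came to between 14.6 M (3KR) and 30.8 M (2KR). At that depth, 1 FPKM for a gene of 2 kb corresponds to between 29.2 and 61.6 fragments. The estimate rests on the annotated transcript lengths, so no counting interval is given.

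The values were used as deposited and compared as log2(FPKM + 0.5). In each comparison of 2 libraries, genes with at least 1 FPKM in either library were kept and those at least 2-fold apart were counted. Such a count describes a pair of libraries and carries no test. In all, 14 comparisons were made. The named genes were, for each of the 8 main comparisons, the 10 with the largest positive and the 10 with the largest negative difference among genes with at least 5 FPKM in either library, leaving out predicted genes, pseudogenes, families of small RNAs recognised by name (Y RNAs not among them), mitochondrial genes, histones and antigen receptor segments. For the 6 other comparisons 5 each way were taken, for each term of the fit below 10 each way, and from each gene list up to 6 members with the largest difference. Where a gene is listed at 0 in 1 library, no fold is given.

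Of 52 gene lists, 27 cover pathways and 25 cover cell types, gut regions and neighbouring organs. In each comparison a list was described by the median log2 difference of its measured members and by its percentile among 10000 random lists of the same size, drawn from 20 bins of mean expression. A list was said to stand apart from random lists below the 2.5th or above the 97.5th percentile. The lists for mast cells and eosinophils, erythroid cells and skeletal muscle had fewer than 4 members with a mean of at least 1 FPKM and got no percentile, which left 49. Members of a list are co-regulated, so the percentile is a description and not a test of the diet.

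The 8 libraries from DSS-treated mice form a factorial of day, methionine deficiency and tryptophan plus niacin deficiency with 1 library per cell. A linear model with day, both diet factors and their interactions with day was fitted to 17577 genes with a mean of at least 1 FPKM, using limma 3.58.1 with a mean-variance trend in R 4.3.3. Each diet coefficient compares 2 libraries with 2 others of the same day. The 2 residual degrees of freedom come from the interaction between both diet factors, assumed to be 0, so a true interaction enters the error. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. No model including the library without DSS was fitted.

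Log2 differences that share no library were correlated across 17631 genes. For differences that share a control, the correlation and covariance are given beside values simulated for unchanged libraries of equal spread. That spread was taken per gene from the residuals of the fit above. Genes are not independent replicates, so these correlations carry no p.

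The fit was tested on simulated data in which 200 of 17577 genes were changed, 50 at each of 4 sizes. For tryptophan and niacin deficiency at day 28, the fit called 0 of 50 genes changed by 1 on the log2 scale, 8 of 50 changed by 2, 39 of 50 changed by 4 and 47 of 50 changed by 8, and 11 unchanged genes were called as well. For methionine deficiency at day 28 the numbers were 0, 15, 38 and 47, with 15 unchanged genes called. At day 33 they were 0, 8, 37 and 47 with 6 unchanged genes for methionine, and 0, 13, 35 and 45 with 9 unchanged genes for tryptophan and niacin. Random lists with no shift stood apart in 17 of 200 cases with 10 members and in 12 of 200 with 20 members, and lists shifted by 1 in 160 and 188 of 200.

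The alternatives were a pseudocount of 1 or 0.1, no floor or a floor of 5 FPKM, median-of-ratios scaling over 7809 genes with at least 5 FPKM in every library, a fit without the trend, a fit with diet effects common to both days, leaving out each library in turn, list means, and Spearman correlations. The comparisons, lists, naming rule and these alternatives were chosen before the data were examined. A fit without 2K and 3K was added after the data had been seen. Across settings a count was taken as changed beyond 1.5 times the original, a correlation beyond 0.1 or on a change of sign, and a gene's log2 difference beyond 0.5. Count-based methods were not run because the values are FPKM. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps. Values of 3 single genes are not reported here.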

Results

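The series measured gene expression in the intestinal tract of mice in a model of inflammatory bowel disease, in which dextran sulfate sodium (DSS), a polymer that injures the gut epithelium, is given in the drinking water. It asks how diets lacking methionine, or tryptophan and niacin, or all 3 nutrients act on the gut in this model. DSS was offered from day 18 in 8 of the 9 conditions. At day 28, tissue was taken from mice on a normal diet (R), a methionine-deficient diet (1K), a diet deficient in tryptophan and niacin (2K) and a diet deficient in all 3 (3K). At day 33, it was taken from mice kept on the normal diet (RR) and from mice moved at day 28 from each deficient diet back to the normal one (1KR, 2KR and 3KR). The control without DSS on the normal diet (C) was collected at day 34. Each condition has 1 library, so no difference between 2 libraries can be set against a spread between replicates, and every fold below describes those libraries.

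Between 15908 (2KR) and 17256 (R) genes had at least 1 FPKM, and the summed FPKM ran from 597541 (C) to 973592 (3KR). The most abundant RNA in every library was Rn7sk, a small nuclear RNA that restrains transcription elongation, with 4.15% (2K) to 9.68% (3KR) of the summed FPKM. Small RNAs held 49.7% of the summed FPKM in 3KR and between 14.1% and 25.6% in the other 8 libraries, and 3KR also had the lowest estimated depth, 14.6 M fragments. The closest libraries were RR and 1KR, with 1022 genes at least 2-fold apart, then 1KR and 2KR with 1042 and RR and 2KR with 1081. The farthest were 2K and 1KR, with 6170. The first principal component carried 40.5% of the variance and set apart 2K (loading 0.75) and 3K (0.45), and the second carried 17.5% and set apart 3KR (0.81).

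Several libraries differed in transcripts of neighbouring organs and of gut regions, which stand beside every comparison below. The pancreatic acinar list held 7.31% of the summed FPKM in 2K and 9.63% in 3K, against at most 0.625% elsewhere. That remainder was mostly Zg16, a secretory granule lectin that is also on the goblet cell list, with 3402 FPKM in R, and 8 list members had at least 1 FPKM in C. The stomach list held 2.35% in 2K, 0.00924% in 3K and at most 0.000382% in the other 7 libraries, and none (0) of its genes reached 1 FPKM in C. The liver list held 5.42% in 2K and at most 0.081% elsewhere, although all 13 measured genes on it had at least 1 FPKM in C. The ileal enterocyte list held 0.712% in C and 0.464% in R, but between 0.0196% (2K) and 0.127% (3KR) in the other 7 libraries.

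**Figure D1:**
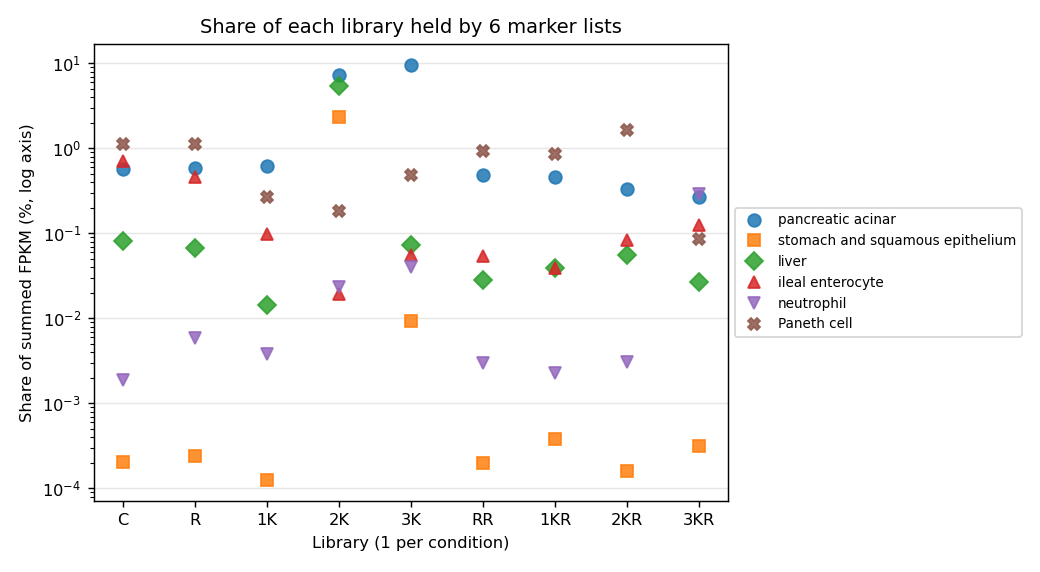
Share of the summed FPKM (percent, log axis) held by 6 marker lists in each of the 9 libraries, 1 point per list and library. Pancreatic acinar transcripts reached 7.31% in 2K and 9.63% in 3K, and neutrophil transcripts 0.291% in 3KR.

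DSS on the normal diet, at day 28 (R) and at day 33 (RR), was compared with the single control without DSS. That control was collected at day 34, so collection day differs along with DSS. At day 28, R had 808 genes at least 2-fold higher and 586 at least 2-fold lower than C. Markers of macrophages and of tissue damage were among the highest ranked: Gpnmb, a glycoprotein of activated macrophages, was at 17.7 against 0.198 FPKM (log2 difference 4.70), Mmp12, macrophage elastase, at 14.0 against 0.624 (3.69), Saa3, an acute phase protein, at 30.6 against 2.51 (3.37) and S100a8, a calprotectin subunit of neutrophils (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035, plus strand), at 5.57 against 0.121 (3.29). Of 22 measured antimicrobial and epithelial defence genes, 7 were at least 2-fold higher and 1 lower, with Nos2 (inducible nitric oxide synthase) at 95.2 against 17.2 FPKM and Lcn2 (lipocalin 2) at 9.72 against 1.47. The neutrophil list had 6 of 16 genes at least 2-fold higher and 0 lower, the macrophage list 6 of 21 and 0, and the cytokine list 7 of 24 and 0, the last including Socs3 (22.7 against 4.79), a feedback inhibitor of cytokine signalling. Plasma cell genes had a median of 0.90, with Igkc, the kappa light chain, at 2670 against 935 FPKM. All 23 cholesterol synthesis genes were lower in R than in C, though only 2 by at least 2-fold, with a median of -0.38 and Insig1, a sterol sensor, at 10.4 against 23.2.

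Clock genes differed more between R and C than any of the other 48 lists, with a median of 1.74, 10 of 17 genes at least 2-fold higher and 3 lower. Dbp, a clock output factor (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203, plus strand), was at 46.9 against 1.81 FPKM. Per3 was at 11.7 against 1.44, and Nr1d1, a repressor in the clock loop, at 90.5 against 14.9. Arntl, the clock activator that Nr1d1 represses (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126, plus strand), was at 3.53 against 23.0. The split was also present between RR and C, where the clock median was 1.51, Dbp was at 61.1 FPKM and Arntl at 4.44. In all 8 DSS libraries Dbp was above and Arntl below its level in C, with 3KR nearest to C for Dbp, at 11.3 FPKM. The hour at which tissue was collected is not given in the sources used here.

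**Figure D2:**
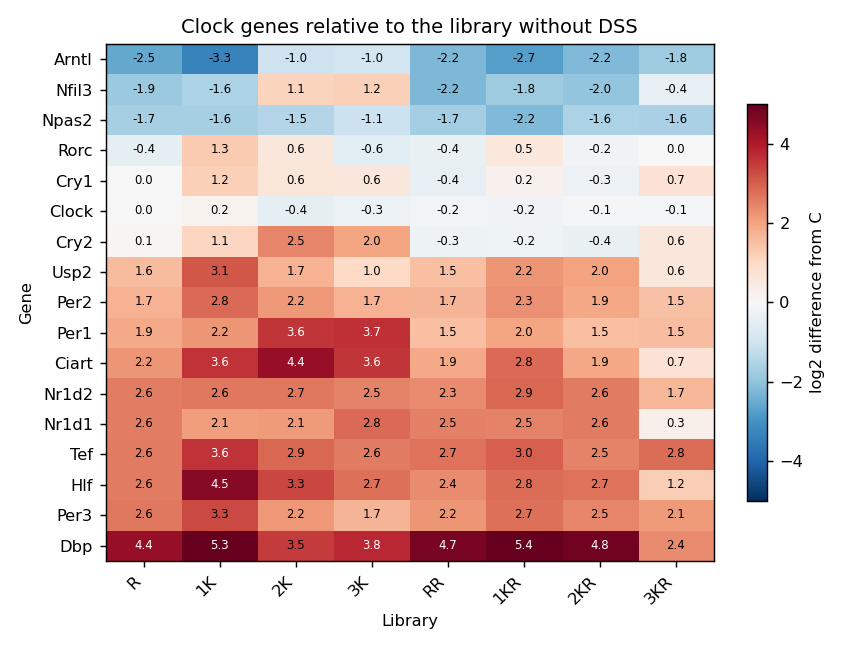
Log2 difference of 17 clock genes (genes down the side) between each of the 8 DSS libraries (columns) and the library without DSS. Dbp was higher in each of the 8 (4.36 in R and 4.73 in RR), and Arntl was lower (-2.54 in R and -2.25 in RR).

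At day 33, RR had 1209 genes at least 2-fold higher and 1047 lower than C, which became 1049 and 1258 after median-of-ratios scaling. Genes that vary along the length of the gut were among the largest differences, beside liver genes such as Alb (3.36 against 167 FPKM, -5.44), the clock gene Dbp and the macrophage gene Gpnmb (14.0 against 0.198). Fabp6, the ileal bile acid binding protein (ENSMUSG00000020405, chromosome 11, 43596049 to 43601540, minus strand), was at 2.90 FPKM in RR and 3486 in C (-10.00). Fgf15, the ileal hormone that restrains bile acid synthesis, was at 1.79 against 90.4, and Slc10a2, the ileal bile acid transporter, at 1.58 against 43.1. Fabp1, a fatty acid binding protein of the proximal intestine (ENSMUSG00000054422, chromosome 6, 71199827 to 71205023, plus strand), was at 1525 against 55.1 (4.78). The duodenal list had a median of 1.82, with Gata4 at 70.9 against 14.2, and the ileal list a median of -1.18 with 4 of 7 genes at least 2-fold lower. Slc2a2, a glucose and fructose transporter, was at 203 against 6.17, and 14 of 21 xenobiotic metabolism genes were at least 2-fold higher and 0 lower, led by Cyp2b10 at 202 against 7.09 and Cyp3a11 at 722 against 86.9. Lipid absorption genes had 9 of 17 at least 2-fold higher and 0 lower (median 1.01), and cholesterol synthesis genes 12 of 23 at least 2-fold lower and 0 higher (median -1.01). T and NK cell genes were higher, with a median of 0.98 and Gzmb (granzyme B) at 13.4 against 1.40 FPKM. The neutrophil list had 3 of 16 genes at least 2-fold higher.

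The library R differed from RR in the same regional genes, although both had DSS and the normal diet. Against R, RR had 975 genes at least 2-fold higher and 953 lower, or 842 and 1165 after median-of-ratios scaling. Fabp6 was at 2.90 against 1946 FPKM (-9.16), the ileal median was -1.45 and the duodenal median 1.59. Reg1, a regenerating-family lectin of the proximal gut and pancreas, was at 244 against 3.19, Nos2 at 3.13 against 95.2, and Cyp3a11 at 722 against 54.3, with 16 of 21 xenobiotic genes at least 2-fold higher. The day 33 comparisons below take RR as their control and the day 28 comparisons take R.

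Methionine deficiency at day 28 was examined as 1K against R, which had 1302 genes at least 2-fold higher and 1567 lower. The highest ranked gene was the sulfotransferase gene Sult6b2 (137 against 0.199 FPKM, 7.62), followed by Gml2 (4.97) and Gml (4.70). Fat-handling genes of the absorptive epithelium were also among the 10 highest. Fabp1 was at 2941 against 113 FPKM (4.69), Apoa4, an apolipoprotein of chylomicrons, at 9730 against 498 (4.29) and Apoc2, the lipoprotein lipase cofactor, at 2944 against 211 (3.80). Some of these genes were also higher than in R without a deficient diet: in RR, Sult6b2 was at 15.0 and Fabp1 at 1525 FPKM. The lipid absorption list held 4.58% of the summed FPKM in 1K and 3.07% in RR, against 1.39% in R and 1.35% in C. Of 17 lipid absorption genes 11 were at least 2-fold higher and 0 lower (median 1.37), and of 22 enterocyte genes 11 were higher and 1 lower (median 1.08), with Slc2a2 at 357 against 32.9. Olfm4, a marker of crypt base stem cells (ENSMUSG00000022026, chromosome 14, 79984081 to 80023139, plus strand), was at 3.51 against 214 FPKM (-5.74). Paneth cell genes had 11 of 14 at least 2-fold lower and 0 higher (median -1.93), with Ang4 at 14.1 against 141, and 38 of 40 cell cycle genes were lower, 10 of them by at least 2-fold, with Mki67 at 8.37 against 21.9.

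Matrix, B cell, plasma cell and macrophage genes were also lower in 1K. Extracellular matrix genes had 24 of 29 at least 2-fold lower and 0 higher (median -1.48), with the collagen genes Col1a1 at 4.18 against 46.7 FPKM and Col3a1 at 23.7 against 237. The fibroblast and mesenchyme list, which shares 4 of 17 genes with other lists, had a median of 7.26 FPKM in 1K and 20.5 in R. B cell genes had 14 of 18 at least 2-fold lower (median -1.51), with Ighm at 19.5 against 178, plasma cell genes had 8 of 12 (median -1.67) and macrophage genes 9 of 21 (median -0.96), with Lyz2 at 31.4 against 260. T and NK cell genes did not stand apart from random lists (median 0.11, and below 0 after median-of-ratios scaling). Adipocyte genes had 11 of 15 at least 2-fold lower, with Adipoq (adiponectin) at 0.85 against 20.7, and liver genes 11 of 13, with Alb (albumin; ENSMUSG00000029368, chromosome 5, 90460897 to 90476602, plus strand) at 1.08 against 85.3. Defence genes went both ways: Reg3b, a bactericidal lectin (ENSMUSG00000071356, chromosome 6, 78370657 to 78373466, plus strand), was at 35192 against 6070 FPKM and Saa1 at 231 against 23.2, but Pla2g2a was at 351 against 2110. The ileal list had a median of -1.15 (Fabp6 at 342 against 1946) and the duodenal list 1.33 (Gip at 181 against 43.7). Neutrophil genes had 3 of 16 higher and 3 lower by 2-fold (median -0.14).

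Among genes tied to the missing nutrient, the methionine cycle and transsulfuration list had a median of -0.11 in 1K and stood apart from random lists on the low side, with 2 of 26 genes at least 2-fold higher and 5 lower. The polyamine synthesis list stood apart on the high side (median 0.56). Cdo1 (cysteine dioxygenase) was at 4.50 against 22.5 FPKM, and Gclc, which makes the glutathione precursor, at 98.0 against 31.4. The amino acid response list, targets of the transcription factor ATF4, had a median of 0.08 and did not stand apart from random lists, with Trib3 at 16.5 against 5.14 and Nupr1 at 7.51 against 39.9. Median-of-ratios scaling moved the median of all genes in 1K against R from 0.03 to -0.16 and the share of higher genes among those counted from 45.4% to 31.1%. It also moved that median from -0.02 to -0.13 for RR against C, from 0.03 to 0.15 for 3KR against RR and from -0.04 to 0.15 for 3K against 1K.

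The diet deficient in tryptophan and niacin was examined as 2K against R, which had 2801 genes at least 2-fold higher and 2693 lower. The highest ranked genes were digestive enzymes of the pancreas and products of the stomach lining. Ctrb1, chymotrypsinogen B (ENSMUSG00000031957, chromosome 8, 111686519 to 111691010, minus strand), was at 24692 against 1.36 FPKM (13.70). Tff1, the gastric trefoil peptide (ENSMUSG00000024032, chromosome 17, 31161395 to 31165277, minus strand), was at 8134 FPKM and listed at 0 in R, and Pgc, progastricsin, was at 4846 and listed at 0 in R. Of 26 acinar genes 25 were at least 2-fold higher and 1 lower (median 9.27), all 10 measured stomach genes were at least 2-fold higher (median 9.93) and so were all 13 liver genes (median 7.49), with Alb at 15459 against 85.3.

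Tryptophan and NAD metabolism differed in 2K together with those organ genes. The kynurenine and NAD synthesis list had 8 of 16 genes at least 2-fold higher and 3 lower (median 0.89), and the higher ones included enzymes that are abundant in liver: Tdo2 (tryptophan dioxygenase) at 242 against 2.05 FPKM, Haao at 43.2 against 2.04 and Qprt, which makes NAD precursors from quinolinate, at 13.4 against 0.497. The methionine cycle list had 12 of 26 higher and 1 lower, led by Mat1a (709 against 2.31), Gnmt (332 against 1.11) and Bhmt (365 against 1.41), again enzymes abundant in liver. The amino acid response list had 13 of 36 higher and 1 lower (median 0.76), with Atf5 at 38.3 against 8.68 and Gpt2 at 77.0 against 7.16. Asns, asparagine synthetase (ENSMUSG00000029752, chromosome 6, 7675169 to 7693254, minus strand) and a textbook target of this response, was at 50.7 against 26.1, a gene singled out after its values were seen. Nupr1, also on the Paneth cell list, was at 496 against 39.9. What the organ transcripts of 2K add to the amino acid response list was not tested.

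Several epithelial lists were lower in 2K, but the duodenal list had 7 of 9 genes at least 2-fold higher and 1 lower (median 1.96), and the tuft cell (0.76) and enteroendocrine (0.42) lists were higher too. Fabp6 was at 0.282 against 1946 FPKM (-11.28), Cubn, the ileal cobalamin receptor, at 0.304 against 283 (-8.46) and Olfm4 at 1.03 against 214 (-7.13). The ileal list had 5 of 7 genes at least 2-fold lower, the Paneth list 12 of 14 (median -3.26; Lyz1 at 109 against 2149), the goblet list 11 of 16 (median -1.69; Muc2 at 765 against 7863) and the enterocyte list 13 of 22. All 40 cell cycle genes were lower, 31 by at least 2-fold (median -1.46), with Top2a at 3.49 against 33.6. Amino acid transporters had 10 of 16 at least 2-fold lower and 1 higher (median -1.29), with Slc15a1, the peptide transporter, at 57.5 against 396, while Slc38a3, a glutamine transporter also made in liver, was at 141 against 1.74. The serotonin list had a median of -0.97, with Maoa at 8.75 against 116, and 9 of 10 genes of MHC class II presentation were at least 2-fold lower, with Cd74 at 95.5 against 315. The aryl hydrocarbon receptor list (median 0.51) did not stand apart from random lists.

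Neutrophil and cytokine genes were higher in 2K than in R, whereas interferon response genes had 10 of 38 at least 2-fold lower and 2 higher (median -0.44). The neutrophil list had 10 of 16 genes at least 2-fold higher and 0 lower (median 1.49), with S100a8 at 59.5 against 5.57 FPKM and Ltf (lactoferrin) at 12.1 against 1.18. Red cell genes, singled out after their values were seen, were higher too, with Hbb-bs (beta globin) at 20.5 against 10.8 and Alas2 (heme synthesis in red cells) at 11.6 against 5.40, and blood in the day 28 samples was not tested as a source. The cytokine list had 19 of 24 higher and 0 lower (median 1.40), with Cxcl1, a neutrophil-attracting chemokine, at 19.8 against 0.402 and Il1b at 11.1 against 0.970. Lcn2 was at 3026 against 9.72 and Saa1 at 5432 against 23.2, both also acute phase products of liver.

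The diet deficient in all 3 nutrients, 3K against R, had 2192 genes at least 2-fold higher and 2538 lower. Ctrb1 was at 32274 against 1.36 FPKM (14.09) and 25 of 26 acinar genes were at least 2-fold higher (median 9.03), as in 2K, but stomach genes had a median of 0.35 and liver genes of 0.58. Tff1 was listed at 0 in 3K, and Alb was at 81.7 FPKM against 85.3 in R. The amino acid response list had 9 of 36 genes at least 2-fold higher and 1 lower (median 0.46), with Slc7a5, a transporter of large neutral amino acids, at 23.6 against 3.78 and Slc7a11, the cystine transporter, at 5.47 against 1.62. What the pancreatic transcripts of 3K add to this list was not tested. The methionine cycle list had a median of 0.13 and the kynurenine and NAD list of -0.15, and neither stood apart from random lists. In the latter 0 of 16 genes were at least 2-fold higher and 5 lower, with Ido1 at 0.733 against 5.21 and Nadsyn1, which makes NAD, at 7.16 against 26.8.

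In 3K the neutrophil list had 12 of 16 genes at least 2-fold higher and 0 lower (median 1.68; S100a8 at 73.4 against 5.57 FPKM), and the cytokine list 19 of 24 and 0 (median 1.48; Cxcl2 at 31.1 against 0.809). The red cell genes Hbb-bs and Alas2 were at 72.6 and 33.2 FPKM in 3K, against 10.8 and 5.40 in R. Slc4a1 (2.76 against 0.203) and Hba-a1 (1.41, and listed at 0 in R) were higher too. Blood as a source of the neutrophil transcripts of 3K was not tested and stays open. Defence genes had a median of 1.80, with Dmbt1 at 4138 against 206 and Nos2 in the other direction at 1.72 against 95.2. Interferon response genes had 10 of 38 at least 2-fold lower and 0 higher (median -0.73; Oasl2 at 5.29 against 16.1). Goblet genes had 12 of 16 lower (median -1.98; Clca1 at 107 against 1362), Paneth genes 10 of 14 (median -1.23) and xenobiotic genes 11 of 21 (median -1.21). Olfm4 was at 0.916 against 214 and Fabp6 at 88.6 against 1946, and the duodenal median was 2.21. Genes of enteric neurons and glia had 9 of 10 at least 2-fold higher (median 1.74; Ret at 15.8 against 1.96) and endothelial genes 10 of 15 (median 1.13; Lyve1 at 31.5 against 7.11). Against 1K, 3K had 2785 genes higher and 2774 lower, a share of 50.1% higher that became 61.5% under median-of-ratios scaling, and all 29 extracellular matrix genes were at least 2-fold higher in 3K, with Col4a1 at 159 against 29.4. The list medians of fibroblasts (25.8 against 7.26 FPKM) and smooth muscle (36.1 against 26.5) were higher in 3K too. Against 2K, 3K had 1107 higher and 1742 lower, and the liver and stomach lists were the ones with the lowest medians (-6.97 and -8.29).

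**Figure D3:**
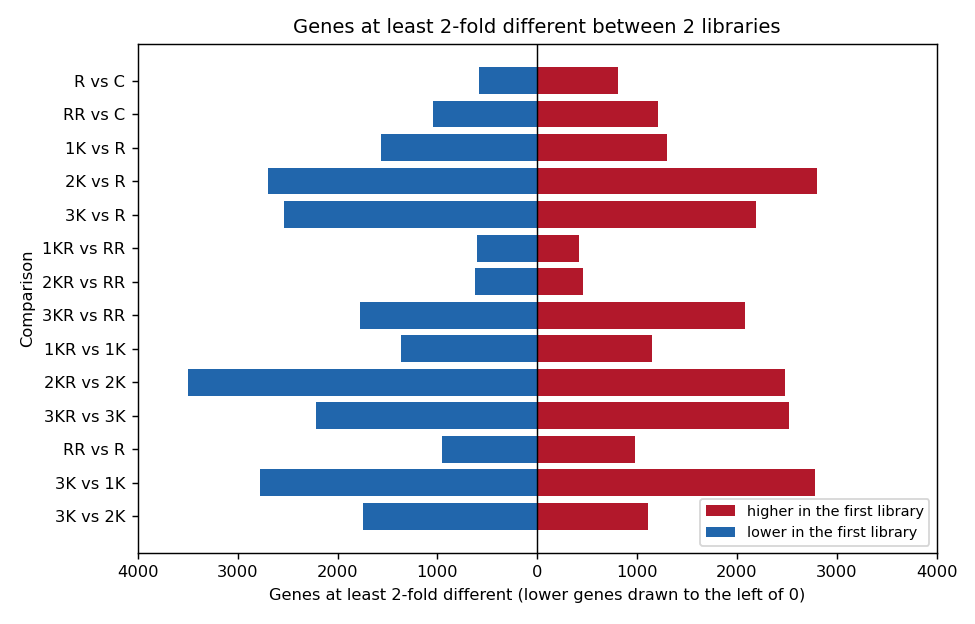
Number of genes at least 2-fold higher (right) or lower (left) in the first library of each of the 14 comparisons. The largest total was 5983 for 2KR against 2K and the smallest 1022 for 1KR against RR.

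Return to the normal diet was examined against RR at day 33 and against the deficient library at day 28. The latter comparisons change collection day together with diet. RR against R, with no change of diet, already had 975 genes at least 2-fold higher and 953 lower. The library 1KR had 422 genes at least 2-fold higher and 600 lower than RR. Interferon response genes were slightly higher, with 37 of 38 higher, 6 of them by at least 2-fold (median 0.53; Ifi44 at 6.94 against 2.06 FPKM). Plasma cell genes had a median of 0.62 (Igha at 1810 against 1110) and T and NK cell genes of 0.47 (Gzmb at 25.7 against 13.4). Ccl21a, a chemokine of lymphatic vessels and lymphoid tissue, was at 16.9 against 0.160, and Cyp1a1, a target of the aryl hydrocarbon receptor, at 10.6 against 1.34. The macrophage list had a median of -0.25, with 1 of 21 genes at least 2-fold lower and 0 higher. Among single genes, Gpnmb was at 0.426 against 14.0 (-3.97), Mmp12 at 0.338 against 11.1 (-3.79), Saa3 at 2.07 against 16.8 and Lyz2 at 72.5 against 159. The amino acid response list had a median of 0.26 with 0 of 36 genes 2-fold apart, the acinar list had 7 of 26 genes at least 2-fold higher (Ctrb1 at 5.80 against 0.237) and the liver list 7 of 13 (Alb at 30.3 against 3.36).

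Against 1K, 1KR had 1150 genes at least 2-fold higher and 1362 lower. Olfm4 was at 202 against 3.51 FPKM (5.66), and 11 of 14 Paneth genes were at least 2-fold higher (median 1.52; Lyz1 at 1516 against 484). Reg3b was at 1132 against 35192 and Reg3g at 758 against 10668, both bactericidal lectins. Fabp6 was at 0.545 against 342, with an ileal median of -1.20. In RR against R, with no change of diet, Fabp6 was lower too (2.90 against 1946 FPKM).

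The library 2KR had 455 genes at least 2-fold higher and 626 lower than RR, and interferon response genes set it apart. Of 38 such genes 23 were at least 2-fold higher and 1 lower (median 1.11). Oas1a, an antiviral RNA sensor, was at 58.9 against 8.39 FPKM, Ifit3 at 19.1 against 1.73, Rsad2 (viperin) at 24.7 against 2.77 and Ifit1 (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009, plus strand) at 78.3 against 9.38. T and NK cell genes were lower, 20 of 22 of them, but only 1 by 2-fold (median -0.53; Cd3d at 0.721 against 3.95). Ido1, which both interferon and tryptophan catabolism lists hold, was at 3.06 against 10.5. Paneth genes had a median of 0.87 (Defa17 at 338 against 150), and 39 of 40 cell cycle genes were higher, 0 of them by 2-fold (median 0.48; Mki67 at 23.3 against 14.7). Xenobiotic genes had 9 of 21 at least 2-fold lower and 0 higher (Cyp3a11 at 131 against 722). Fabp6 was at 255 against 2.90 and Alb at 72.9 against 3.36, with a liver median of 1.59.

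Against 2K, 2KR had 2485 genes at least 2-fold higher and 3498 lower. The lower genes were led by Ctrb1 (0.560 against 24692 FPKM), Tff1 (0.375 against 8134) and Pgc (0.074 against 4846). The higher ones included Olfm4 (274 against 1.03) and Enpp7, the intestinal sphingomyelinase (554 against 1.81). Of 38 interferon genes 32 were at least 2-fold higher (median 2.16; Isg15 at 89.0 against 2.57), and of 40 cell cycle genes 35 were (median 1.81).

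The library 3KR had 2081 genes at least 2-fold higher and 1777 lower than RR. The highest ranked gene was Car1, described below, followed by Stfa2l1, Stfa2, S100a8 and S100a9. All 16 neutrophil genes were at least 2-fold higher (median 5.09): S100a8 was at 1273 against 1.54 FPKM (9.29), S100a9 at 751 against 0.724 (9.26) and Ngp at 89.7 against 0.314. Stfa2l1 and Stfa2, stefins of myeloid cells, were at 377 and 329 FPKM and listed at 0 in RR. The cytokine list had 20 of 24 higher and 1 lower (median 3.22), with Cxcl2 at 303 against 1.75, Il1b at 248 against 2.88 and Osm (oncostatin M) at 27.9 against 0.108. Lcn2 was at 208 against 1.69. Of the 16 measured genes on the neutrophil list, 3 are also on another list and 4 reached 1 FPKM in C. The immunoglobulin G genes Ighg1 (638 against 2.60) and Ighg2b (237 against 4.06) were higher, while Igha was at 400 against 1110. Interferon genes had 21 of 38 at least 2-fold lower and 0 higher (median -1.02, with Isg15 at 2.29 against 13.6). Extracellular matrix genes had 17 of 29 higher and 0 lower (median 1.07, with Lox at 9.37 against 0.989). The list medians of fibroblasts (25.2 against 12.6 FPKM) and smooth muscle (61.5 against 39.1) were higher too.

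Regional genes also set 3KR apart from RR. Car1, carbonic anhydrase 1 of the colon (ENSMUSG00000027556, chromosome 3, 14766216 to 14808368, minus strand), was at 1151 FPKM and listed at 0 in RR, Retnlb, a goblet cell product of the colon, at 115 and listed at 0, and Fabp6 at 658 against 2.90. The colonic list had 9 of 15 genes at least 2-fold higher and 2 lower (median 1.32). The duodenal list had 7 of 9 lower (median -2.96; Gip at 9.31 against 136), the Paneth list 13 of 14 (median -2.85; Lyz1 at 193 against 2048), the enterocyte list 14 of 22 (median -1.33; Lct, lactase, at 32.6 against 472) and the lipid absorption list 14 of 17 (median -1.92; Fabp1 at 127 against 1525). Cholesterol synthesis genes had 18 of 23 at least 2-fold higher and 0 lower (median 1.57; Sqle at 41.3 against 8.01). The serotonin list had a median of -1.10 (Ddc at 21.4 against 132) and the kynurenine and NAD list of -0.82 (Naprt at 28.7 against 88.2). This library had the largest small RNA share and the lowest depth of the 9.

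Against 3K, 3KR had 2520 genes at least 2-fold higher and 2218 lower. Neutrophil genes had 14 of 16 at least 2-fold higher (median 3.16; S100a8 at 1273 against 73.4 FPKM), the colonic median was 2.05 and Ctrb1 was at 9.83 against 32274.

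**Figure D4:**
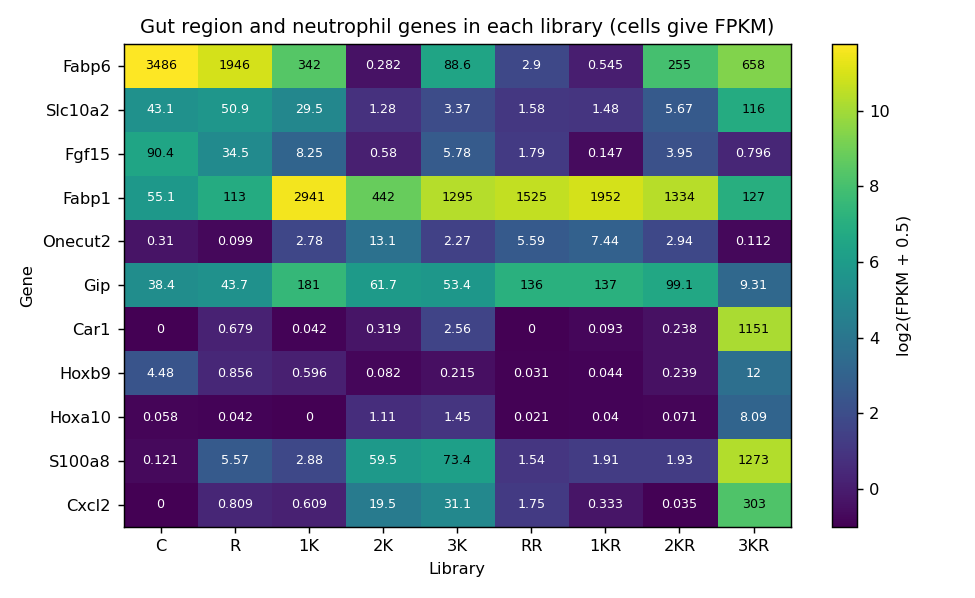
FPKM of 11 gut region and neutrophil genes (down the side) in the 9 libraries (columns), coloured by log2(FPKM + 0.5). Fabp6 ran from 0.282 in 2K to 3486 in C, and Car1 and S100a8 were highest in 3KR, at 1151 and 1273.

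The 8 DSS libraries were also fitted together with limma, which sets each diet factor against the interaction of both factors. For tryptophan and niacin deficiency at day 28, 33 genes were called, 30 higher and 3 lower, among 3380 with an unadjusted p under 0.05. The 10 named higher genes were all products of the exocrine pancreas: Ctrb1 rose by 14.09 (log2; SE 0.285, adjusted p 0.00111), Prss2, a trypsinogen, by 12.58 (SE 0.242, adjusted p 0.00111), and Pnliprp1, a lipase relative, by 11.46 (SE 0.212, adjusted p 0.00111), and the insulin gene Ins2 was among the other called genes (9.22, adjusted p 0.00258). The 3 lower genes, named after their values were seen, were the antisense gene Gm43126 (-4.72, adjusted p 0.0122) and the pseudogenes Gm47217 (-4.77, adjusted p 0.0145) and Gm6378 (-3.69, adjusted p 0.0398). Among the named genes not called, Atoh1, which specifies secretory cells, had a coefficient of -3.02 (adjusted p 0.0788) and Nts, neurotensin, of -4.78 (adjusted p 0.0692). Leaving out any 1 of the 8 libraries (R, 1K, 2K, 3K, RR, 1KR, 2KR or 3KR) left 0 called genes.

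For methionine deficiency at day 28, limma called 0 genes, with 563 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0913. That smallest value belonged to a gene left out by the naming rule, and no named gene was near the threshold after adjustment. The named genes included Socs3 (1.39), Acaa1b, a peroxisomal thiolase (2.02), Fn1, fibronectin (-2.34), C3, complement component 3 (-3.01), and Alb (-6.66). Fn1, C3 and Alb are also products of liver and were highest in 2K (450, 1892 and 15459 FPKM), beside its liver transcripts. The fit without 2K and 3K sets 1K against R alone at day 28 and takes its spread from the day 33 libraries. It therefore cannot show whether the methionine result depends on 2K. For the day 33 libraries 0 genes were called for the methionine history (218 at an unadjusted p under 0.05) and 0 for the tryptophan and niacin history (389). There the named genes, also far from the threshold after adjustment, included Ctrb1 for methionine (3.19) and Reg1 (-5.45) and Lss, a sterol synthesis enzyme (1.31), for tryptophan and niacin.

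Camera at the preset correlation called 25 of 49 lists for tryptophan and niacin deficiency at day 28. The acinar list rose (median 9.35, 20 of 26 members called, 26 adjusted over the list alone, adjusted p 9.5e-40), and with an estimated correlation its adjusted p was 0.535, while fry's directional test gave an adjusted p of 0.00213, the only list it called. Fry's mixed test, which asks for changes in either direction, called 5 lists: acinar, amino acid response, plasma cell, goblet cell and enteroendocrine. Goblet cell genes (median -1.84; 9 members adjusted over the list alone), enterocyte genes (-2.16; 11 members), amino acid transport genes (-1.46; 12 members), amino acid response genes (0.53; 5 members), and genes of enteric neurons and glia (1.35; 8 members) were called too, with 0 of their members called over all genes, and so were the liver (5.84; 12 members) and stomach (5.13; 1 member) lists, which stand beside the organ transcripts of 2K. For each of these the adjusted p = 0.861 with an estimated correlation. The neutrophil list (1.77) and the cytokine list (1.56) had 0 members called on either basis and the same adjusted p = 0.861 with an estimated correlation.

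For methionine deficiency at day 28 camera called 18 lists, among them liver (median -4.86; 11 members adjusted over the list alone), enterocyte (0.85; 0 members), lipid absorption (0.67; 0), cholesterol synthesis (0.54; 0), extracellular matrix (-0.58; 1) and the methionine cycle (-0.44; 0), each with adjusted p = 0.839 with an estimated correlation. The liver and methionine cycle calls stand beside the liver transcripts of 2K: the methionine cycle median was -0.56 in 3K against 2K and -0.11 in 1K against R. At day 33 it called 24 lists for the methionine history and 26 for the tryptophan and niacin history. Cholesterol synthesis genes (0.77 and 0.73) and neutrophil genes (2.55 and 2.61) were called higher in both, with 0 members called on either basis, and with adjusted p = 0.887 and adjusted p = 0.808 with an estimated correlation. Both histories share 3KR, in which those genes were highest. With an estimated correlation 0 lists were called for any of these 4 coefficients. With 2 residual degrees of freedom that form of camera has little power, and even the acinar list at day 28 had an adjusted p of 0.535 by it. Its 0 calls therefore do not show that a list is unchanged.

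**Figure D5:**
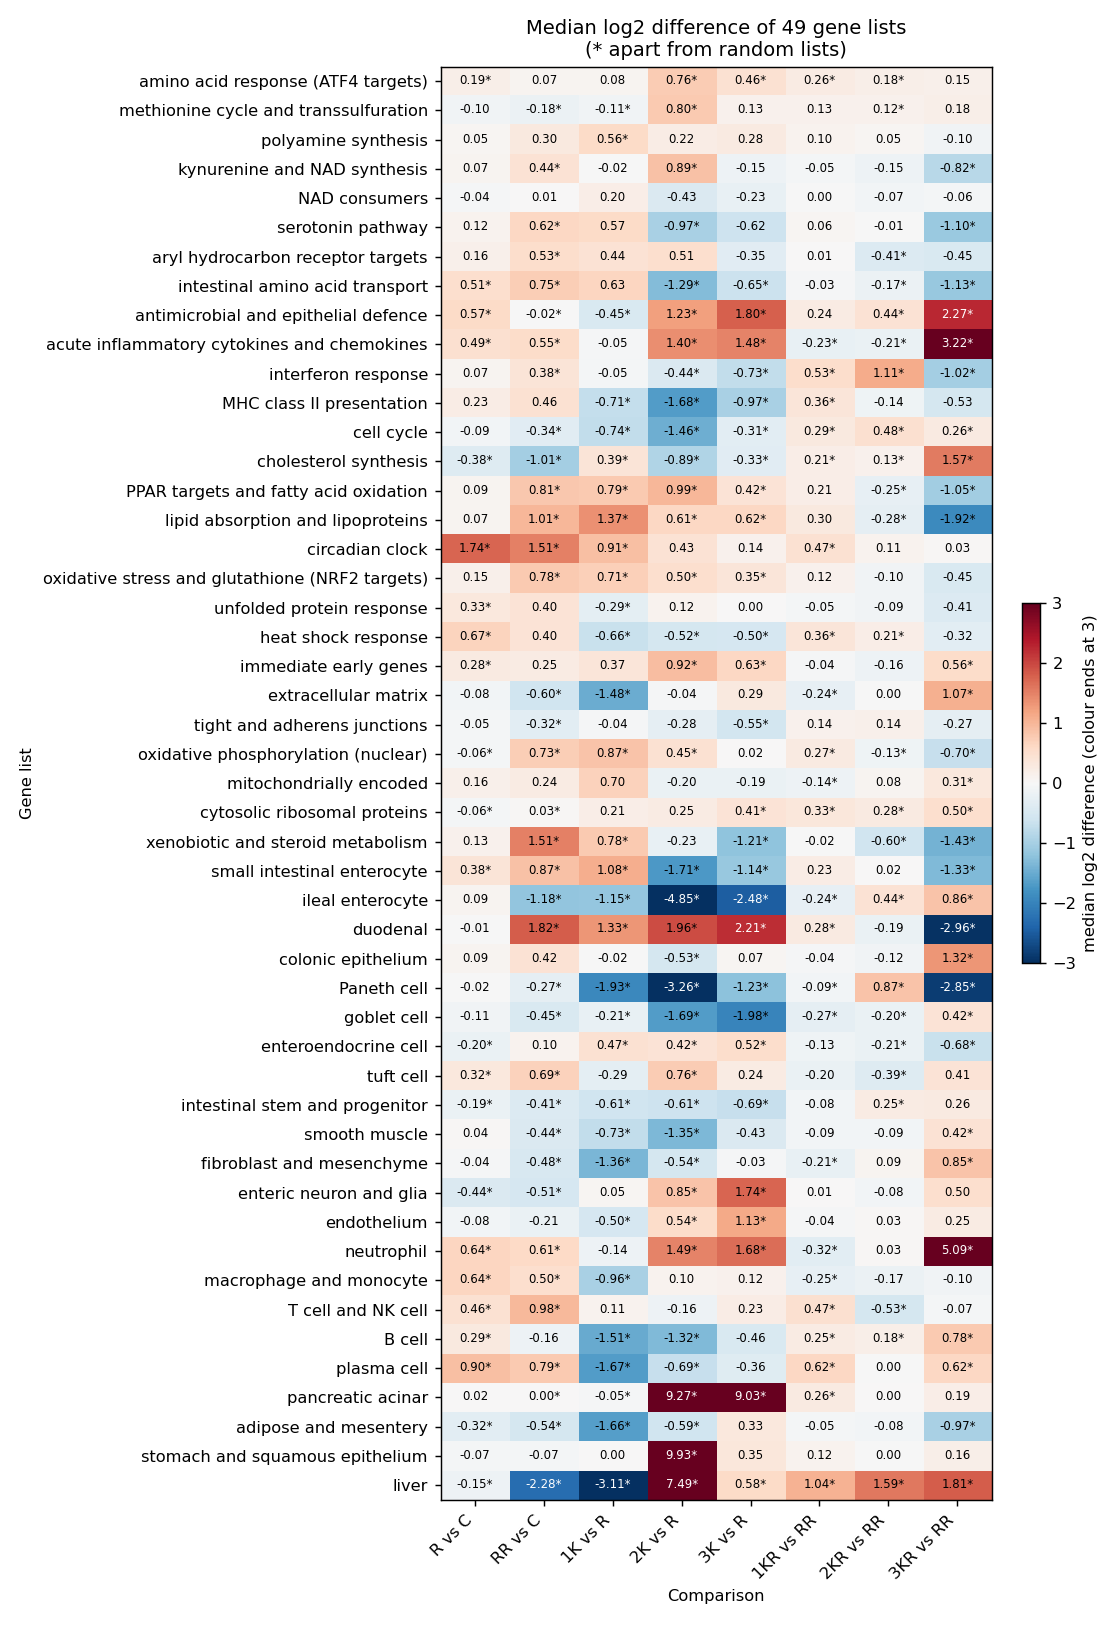
Median log2 difference of 49 gene lists (down the side) in the 8 main comparisons (columns), with an asterisk where the list stood apart from random lists. The neutrophil list reached 5.09 in 3KR against RR, and the interferon list 1.11 in 2KR against RR.

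Differences that share no library were compared across 17631 genes, which are not independent replicates. The difference with tryptophan and niacin deficiency at day 28 was similar without methionine deficiency (2K minus R) and with it (3K minus 1K). The Pearson correlation was 0.44, with 897 genes at least 2-fold higher in both against 284 under independence, and 1048 lower in both against 344. Both differences hold the pancreatic transcripts of 2K and 3K, so diet and tissue cannot be told apart here. The methionine difference at day 28 had a correlation of -0.04 between 1K minus R and 3K minus 2K. In these, 103 genes were at least 2-fold higher in both against 58.6 under independence, and 217 lower in both against 107. The liver and stomach transcripts of 2K enter 3K minus 2K. At day 33 the correlations were -0.12 for the methionine history and 0.03 for the tryptophan and niacin history. Across days the same diet gave 0.06 for 1K, 0.03 for 2K and 0.20 for 3K. Differences that share a control are correlated even when nothing changes, and the simulated value was a correlation of 0.51 with a covariance of 0.447. The simulated spread came from the residuals of the limma fit, which also hold any interaction of the diets. The simulated covariance may therefore be too high. Against R, 2K and 3K had 0.69 with a covariance of 1.14, 1K and 2K had 0.28 (0.375), and 1K and 3K had 0.32 (0.335). Against RR, 1KR and 2KR had 0.53 (0.21), 1KR and 3KR 0.19 (0.132), and 2KR and 3KR 0.33 (0.229). Against C, R and RR had 0.49 (0.289). With 1 library per control the part due to the control cannot be split off.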

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

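The tests of diet for the organ transcripts, of DSS exposure, and of all explanations for the neutrophil genes were chosen only after the result was seen. The effect of tryptophan and niacin deficiency differed between day 28 and day 33 for 26 genes by limma's interaction term, 25 with a lower and 1 with a higher effect at day 33. The lower ones included Ctrb1 (change of the log2 effect -13.47, SE 0.403, adjusted p 0.00488) and Pnliprp1 (-11.34, SE 0.3, adjusted p 0.00488), and the higher one, named after its value was seen, was the antisense gene Gm43126 (6.06, adjusted p 0.0217). Leaving out any 1 of the 8 libraries gave 0 calls. The effect of methionine deficiency differed between the days for 0 genes by limma, with 371 at an unadjusted p under 0.05 against 1587 for tryptophan and niacin.

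Pancreatic transcripts in 2K and 3K, and stomach and liver transcripts in 2K, may come from tissue of these organs in the sample. Of 10 pancreatic genes outside the list, 7 were highest in 2K and 3K, among them the islet hormone genes Iapp (26.7 and 25.6 FPKM, at most 1.66 elsewhere) and Ppy (29.1 and 40.1, at most 2.69). Of 10 stomach and 10 liver genes outside the lists, 9 and 10 were highest in 2K, such as Cldn18 (145 FPKM) and Itih4 (1274 FPKM). These counts had no floor or margin. They include Sox2 (0.379 FPKM in 2K) and Hsd3b5 (0.058), both under 1 FPKM, and Capn8 (6.22 against 5.35 in C). Tryptophan and niacin deficiency as the whole cause is argued against for stomach and liver, because 3K lacked the same nutrients and its list medians against R were 0.35 and 0.58. The diet of 3K also lacked methionine, and whether that could offset such an effect was not tested. For the pancreas that median was 9.03 in the lower of both libraries, so a diet effect and pancreatic tissue cannot be told apart, since the 2 libraries with high levels (list medians of 999 and 974 FPKM) are both from mice on a diet lacking these nutrients at day 28, although 1KR, whose mice never lacked them, had a median of 1.16 FPKM against 0.0585 in RR. Whether such tissue was taken along by chance is not recorded in the sources used here.

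Regional genes differed between libraries as they would if different parts of the gut had been sampled. Posterior Hox genes mark the position along the body axis. For 3KR against RR, all 9 of them with at least 1 FPKM in either library were higher in 3KR, as a more distal segment would give. Their median log2 difference was 2.25, and of this pair of libraries most reached 1 FPKM in 3KR only. Some reached it in other libraries, such as Hoxa10 in 3K (1.45) and Hoxb9 in C (4.48). Hoxc8 was higher in R (5.59) and C (6.35) than in 3KR (2.07). Below 1 FPKM in both 3KR and RR, Hoxc9 (0.298 against 0.015 FPKM) and Hoxd11 (0.964 against 0) were higher in 3KR too. For RR against R the same test had 2 genes at that level, which went opposite ways (median 0.63 in R minus RR). Below it, the other genes were higher in R or listed at 0 in both, such as Hoxb9 (0.856 in R, 0.031 in RR), too low to decide. A more proximal segment in RR therefore cannot be told apart from longer DSS exposure. For the latter, the ileal median of -1.45 rests on 1 library and the day DSS ended is not given in the sources used here. The day 33 libraries with an earlier deficient diet went both ways. Their median FPKM of the ileal list was 66.3 in 2KR and 104.7 in 3KR but 15.8 in 1KR, against 69.3 in R and 18.8 in RR. The summed FPKM of the list was below that of R (2775) in all of them, at 595, 1233 and 281. Their diet history differs from that of RR, so they do not settle the effect of exposure. An earlier deficiency of all 3 nutrients also stays open for 3KR, as untested, because no other library had that history.

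Neutrophil genes in 3KR were weighed against depth, blood, segment and diet history. After median-of-ratios scaling the list median was 5.20. Scaling moves all genes of a library by 1 factor, on the log2 scale -0.08 in 3KR and 0.03 in RR. A shift common to all genes, such as one from the small RNA share, is therefore argued against. Other effects of the lower depth cannot be tested by scaling and stay open. Blood as the whole cause is argued against, because all 4 erythroid genes with at least 1 FPKM in either of these libraries were lower in 3KR than in RR (median -0.57; Alas2 at 4.81 against 7.41 FPKM). For a more distal segment, the median over all posterior Hox genes, without a floor, was 2.07 FPKM in 3KR. At least 50% of it was reached in 0 other libraries, so no library separates segment from diet. Earlier deficiency of methionine, tryptophan and niacin, with a median of 5.09 against RR, and a more distal segment therefore cannot be told apart.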

How the results depend on the processing

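The fit without 2K and 3K was chosen only after the result was seen, and in it limma called 0 genes for each of the 4 terms it could estimate. At day 28 that fit sets 1K against R alone, with a spread from the day 33 libraries, so it could hardly call a gene there. No paired analysis was possible because each condition has 1 library, and the single comparisons cannot be run without their own libraries. With a floor of 5 FPKM fewer genes enter, and the genes at least 2-fold apart fell from 1394 to 708 (R vs C), 2256 to 1302 (RR vs C), 2869 to 1721 (1K vs R), 5494 to 3428 (2K vs R), 4730 to 2762 (3K vs R), 1022 to 480 (1KR vs RR), 1081 to 550 (2KR vs RR), 3858 to 2396 (3KR vs RR), 2512 to 1364 (1KR vs 1K), 5983 to 3733 (2KR vs 2K), 4738 to 2749 (3KR vs 3K), 1928 to 1112 (RR vs R), 5559 to 3377 (3K vs 1K) and 2849 to 1671 (3K vs 2K). Under a pseudocount of 1 or 0.1, no floor and median-of-ratios scaling each count stayed within 1.5 times its original. That scaling moved the median of all genes from 0.03 to -0.16 in 1K vs R, with 45.4% and then 31.1% of the differing genes higher, and from -0.04 to 0.15 in 3K vs 1K, with 50.1% and then 61.5% higher. It moved that median from -0.02 to -0.13 in RR vs C and from 0.03 to 0.15 in 3KR vs RR. Which side held more genes turned in 7 of the 14 comparisons under at least 1 setting: with that scaling in RR vs C (1049 higher, 1258 lower), RR vs R (842, 1165), 2K vs R (2702, 2897) and 1KR vs 1K (1211, 1149), with a floor of 5 in 1K vs R (932, 789), 3KR vs RR (1175, 1221) and 3K vs 1K (1470, 1907), with a pseudocount of 0.1 in RR vs C (1411, 1443), RR vs R (1119, 1388) and 2K vs R (3159, 3196), with a pseudocount of 1 in 3K vs 1K (2208, 2368) and with no floor in RR vs R (1074, 1142). For tryptophan and niacin deficiency at day 28, the 33 called genes became 20 with a floor of 5, 67 without the trend and 1 with an effect common to both days, namely the snRNA Gm25328 (log2 -5.06, adjusted p 0.0334 by limma), named after its value was seen. That fit also gives 1 in place of 0 for the history at day 33. The 26 genes for the change between days became 17 with no floor and 17 with a floor of 5. With each library left out in turn, both counts ranged from 0 to 0, in fits with fewer samples. Camera called 18, 25, 24 and 26 lists for methionine, then tryptophan and niacin, at day 28 and the same at day 33, but 0, 0, 0 and 0 with an estimated correlation, and fry's directional test called 0, 1, 0 and 0. The estimated correlation leaves camera little power at 2 residual degrees of freedom. With means in place of medians, lists apart from random ones numbered 12 for R vs C (23 with medians), 14 for 1KR vs RR (24) and 14 for 2KR vs RR (24), and no list apart in both changed side under any setting. Spearman correlations, with Pearson in brackets, were -0.232 (-0.116) for the methionine history at day 33, 0.19 (0.0604) for 1K and -0.0403 (0.0336) for 2K across days, 0.222 (0.322) for 1K and 3K vs R, 0.0228 (0.192) for 1KR and 3KR vs RR and 0.378 (0.488) for R and RR vs C. Apart from fewer genes or samples, the cause was not tested. The log2 differences of named genes were followed under the alternatives only where they were at least 2-fold. Of these, 4386 stayed within 0.5 of the original and 337 moved further. All kept their sign, which was fixed in advance. A pseudocount or floor cannot reverse a difference, and the scaling factors (log2 -0.082 in 3KR to 0.136 in 1K) are too small to. In 2K vs R the mean had the opposite sign to the median for the colonic and adipose lists. At the depth of 3KR, 1 FPKM for a gene of 2 kb is 29.2 fragments.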

Other observations

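No test was run for these values, and Ghrl, Insl5, Hmox1 and Arg1 were compared across libraries after their values were seen. Nuclear oxidative phosphorylation genes had a median of 0.87 in 1K against R, with 10 of 35 genes at least 2-fold higher and 0 lower (Cycs, cytochrome c, at 66.2 against 22.9 FPKM), of 0.73 in RR against C and of -0.70 in 3KR against RR, where 8 were lower and 0 higher. PPAR targets and fatty acid oxidation genes had 8 of 23 at least 2-fold higher in 1K (median 0.79; Pdk4, which diverts pyruvate from oxidation, at 151 against 17.2), 11 in 2K (median 0.99; Pdk4 at 212) and 9 in 3K (median 0.42; Pdk4 at 165). In 3KR against RR 12 of them were lower and 1 higher (median -1.05). Glutathione and NRF2 genes had 7 of 21 at least 2-fold higher and 1 lower in 1K (median 0.71), and Hmox1, heme oxygenase 1, was at 35.9 in 2K and 38.6 in 3K against 5.30 in R and 1.35 in 1K.

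Heat shock genes had a median of 0.67 in R against C, with 3 of 13 at least 2-fold higher and 0 lower (Hspa1b at 6.42 against 0.848 FPKM), and medians of -0.66 in 1K, -0.52 in 2K and -0.50 in 3K against R. Smooth muscle genes had 15 of 18 at least 2-fold lower in 2K against R (median -1.35; Actg2 at 62.6 against 195) and 6 of 18 in 1K (median -0.73; Synm at 5.44 against 16.9). Hormone genes of the gut differed in several libraries, with Ghrl (ghrelin, made mainly in the stomach) at 535 FPKM in 2K and at most 33.2 in the other 8, beside the stomach transcripts of 2K, and Insl5, a hormone of the distal colon, at 8.78 in 3KR and at most 4.12 elsewhere. Arg1, a urea cycle enzyme of liver and of activated macrophages, was at 420.3 in 2K and at most 9.26 elsewhere. The list of NAD-consuming enzymes did not stand apart from random lists in any of the 8 main comparisons, with medians of -0.43 in 2K and -0.23 in 3K against R.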
